A study of Homo sapiens with 4 samples.

How the data were processed

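Chromatin from BJ-HELT cells, an established human fibroblast line, was sonicated and precipitated with a rabbit polyclonal antibody against H3K9me3, and SOLiD libraries were made from 2 precipitates and 2 inputs, per the labels' protocols. Nothing in the labels says whether the 2 replicates came from separate cultures. Bowtie, a short-read aligner, SICER, a caller of broad enriched regions, and the builds hg19 and GRCh37 are named in the submitters' processing notes, without versions or settings. The read filters, the treatment of reads that match several places, the window and gap settings and the threshold are not given in the sources used here.

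The deposited table is a single list of regions for the whole series, with no header, in which each line holds a chromosome, a start, an end and a whole number. All starts fell on a grid of 200 bp and all ends on the last base of a 200 bp window, no regions overlapped, and the smallest gap between neighbours was 800 bp. The whole number was read as a count of ChIP reads per region as deposited by the authors, with no scaling for length, depth or input. This reading rests on the form of the list, which is that of a SICER island list, and on the values, which were at least 27 and never above 1.77 per bp. Where the authors pooled the libraries before calling is not recorded, and the table gives neither a score per library nor a p-value. Positions are printed from 1, with the end of each region read as its last base. Because the count covers called regions only, library depth is unknown, and no limit of detection could be given.

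Long regions were defined as 10 kb or more and short ones as 1 kb or less. Blocks were runs of neighbouring 5 Mb bins with at least 20 regions each. Density is the count divided by the length in kb. The share of regions on each chromosome has a 95% Wilson interval. Because no genome of the build was used here, chromosome lengths were replaced by the span from the first to the last region, a choice made after the data were examined; it counts unassembled sequence inside the span, such as that of Y, and leaves out sequence before the first region, such as most of the short arm of chromosome 9. The numbers of regions and covered bp per chromosome were compared with 10000 rotations of the whole list around the joined spans (regions placed by midpoint), which keep lengths and spacing. Gaps were compared with 1000 independent placements within each span. Trends along a chromosome were Spearman correlations of density, and of length, with the order of regions, compared with every rotation of the values. Counts at equal length used lengths with at least 10 regions on the chromosome, and on the autosomes where these were compared; each count was divided by the median of its length on the same chromosome for the trend. Medians per chromosome were compared between X with Y and the 22 autosomes by an exact permutation test over chromosomes. Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over 24 chromosomes. These tests treat the list as fixed: they speak of its layout and not of variation between libraries.

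The tests were tried on simulated data. With the real list at a random rotation, 4 of 100 runs called any chromosome. With 5211 regions placed independently and 1 chromosome at 3 times its share, 100 of 100 runs called it, which says nothing of the power for a clustered list. The spacing test called 6 of 100 runs of independent placement, and the trend test called 4 of 100 runs without and 100 of 100 with a rise of 2 SD. The trend runs used independent values and unadjusted p-values. They say nothing of the error rate where neighbouring regions have similar densities.

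The tests, alternatives and naming rule were fixed before the data were examined, except those said to be chosen later. The rule named the 10 longest regions, the 5 with the highest counts and the 5 clusters with the most regions, for the case in which no annotation of the build was at hand. That case held: the only gene table used was on GRCh38, whose positions were not used, since the list is on hg19. Planned tests of 19 gene lists, of annotated features, of position within genes, of distance to centromeres and of repeat content were therefore not run. Remarks on what lies near a region (centromeres, D4Z4, zinc finger genes) are background knowledge and not overlaps computed here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.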

Results

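H3K9me3, the trimethylation of lysine 9 on histone H3 that marks constitutive heterochromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in BJ-HELT cells. BJ-HELT is a line of BJ foreskin fibroblasts immortalized with the catalytic subunit of telomerase (hTERT) and the early region of SV40. Cells were taken at passage 10 to 11, and 4 libraries were made: 2 H3K9me3 immunoprecipitates and 2 input DNA libraries. The question addressed was which regions of the genome carry H3K9me3 in these cells. The values examined here were 1 list of called regions for all libraries together, so no value below has a replicate error, no ChIP replicate could be set against the other, and the input entered only through the calling of the regions. The list held 5211 regions that covered 24.9 Mb. Each region came with a whole-number count, which has the form of the number of ChIP reads in that region but is not named in the list. These counts summed to 2226222 and ranged from 27 to 103161 per region. Their sum covers called regions only, and the depth of each library was not known. Intervals given for shares cover counting error only.

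The largest H3K9me3 regions lay next to centromeres and in the heterochromatin of Y. Among the 10 longest regions, 3 were on Y and 2 on chromosome 21, and chromosomes 1, 4, 8, 10 and 12 had 1 each. The longest spanned 160.2 kb on Y (hg19, 13330001 to 13490200), beside the Y centromere, and held 62783 counts. A second Y region of 107.8 kb followed it (13640801 to 13748600, 36804 counts). Another, of 98.6 kb (58819201 to 58917800), bordered the distal edge of the unassembled heterochromatin of the Y long arm and held 93308 counts. The region with the highest count, 103161 over 66.6 kb, lay on chromosome 10 at 42354801 to 42421400, on the long-arm side of the centromere. A second chromosome 10 region of 80.6 kb (39074401 to 39155000, 41374 counts) lay on the short-arm side of the same centromere. Chromosome 4 carried a region of 77.4 kb next to its centromere (49093001 to 49170400) with 70290 counts. Chromosome 21 carried regions of 105.8 kb (10772001 to 10877800, 46705 counts) and 80.2 kb (9941001 to 10021200, 5080 counts) on its short-arm side. Chromosome 1 carried 125.8 kb at 121350401 to 121476200 (16214 counts), and chromosome 12 carried 73.8 kb at 38081601 to 38155400 (5524 counts), both next to the centromere. The region on chromosome 8, 116.0 kb at 86726401 to 86842400 with 11024 counts, was the exception among the 10 and lay well inside the long arm.

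These few regions held a large part of the count. The 10 longest regions made up 4.12% of the covered length and 17.5% of the total count. The 5 regions with the highest counts, of which 4 were also among the 10 longest, made up 2.04% of the length and 16.9% of the count. Whether repeated sequence held in fewer copies in the build raised the counts of these regions was not tested. The treatment of reads that match several places is not known. Regions of 10 kb or more numbered 344, or 6.60% of the list, and held 33.9% of the length and 65.2% of the count. The typical region was much smaller. The median length was 3400 bp, with quartiles of 1800 and 5200 bp, and the median count was 112, with quartiles of 83 and 174.5. Across regions, which are not independent replicates, longer regions had higher counts (Spearman rho = 0.80). The median density was 36.3 counts per kb, with quartiles of 28.9 and 60.0.

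**Figure D1:**
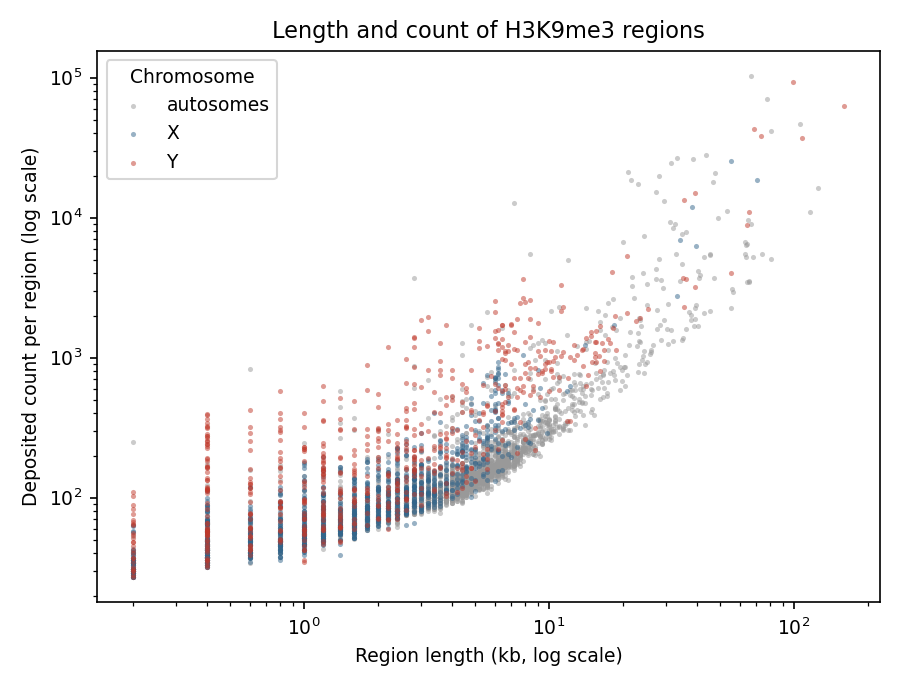
Length of each H3K9me3 region in kb (x axis, log scale) against its deposited count (y axis, log scale), 1 point per region, for autosomes (grey), X (blue) and Y (red). Counts rise with length, and the highest count is on an autosome (chromosome 10).

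The region with the highest density lay at the short-arm end of chromosome 18 (105201 to 112400), with 12755 counts over 7.2 kb, or 1772 counts per kb. Chromosome 10 at 42354801 to 42421400 was next, with 1549 counts per kb. The list median was 36.3, and whether repeated sequence held in fewer copies in the build raised both densities was not tested. The ends of the long arms of chromosomes 4 and 10, where the D4Z4 macrosatellite repeat that contains the DUX4 gene is located, were also marked. On chromosome 4, 20 regions lay between 190196201 and 191037200, covered 274.2 kb and held 13976 counts, and the longest of them measured 65.4 kb. On chromosome 10, 4 regions lay between 135385401 and 135504200 and covered 56.0 kb with 5127 counts. The median density was 48.7 counts per kb at the end of chromosome 4 and 49.5 at that of chromosome 10. Both chromosome ends, and the chromosome 18 region, were chosen for description after their values were seen.

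The sex chromosomes carried more H3K9me3 regions than any autosome. X held 1193 regions, 22.9% of the list (95% Wilson interval 21.8 to 24.1%), and Y held 636, or 12.2% (11.3 to 13.1%). Together they held 35.1% of the regions, 24.5% of the covered length and 36.9% of the total count. Per Mb between the first and last region of each chromosome, Y had 10.7 regions and X 7.84, and the autosomes ranged from 0.26 on chromosome 2 to 6.77 on chromosome 20. Among autosomes, chromosome 20 had 425 regions, chromosome 16 had 402, chromosome 3 had 250 and chromosome 8 had 245, whereas chromosomes 2 and 4 had 63 each. By covered share of the same span, Y led with 5.47%, followed by chromosome 20 with 3.17%, chromosome 21 with 2.92%, chromosome 22 with 2.40% and chromosome 16 with 2.36%, chromosome 19 with 2.04% and X with 1.88%. The first 2.5 Mb of Y held 118 of its regions and 1064.6 kb of the 3.25 Mb covered on Y. That stretch has the same sequence on X in hg19, so short reads there cannot be assigned to either. Without the first 3 Mb of Y, X and Y held 33.4% of the regions.

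Whether these differences exceed what clustered regions give by chance was tested by rotating the whole list around the joined chromosomes 10000 times, a permutation of positions that keeps the spacing. X held 4.46 times the regions of the rotated mean (two-sided permutation test by rotation, p = 0.080, adjusted p = 0.63 by Benjamini-Hochberg over 24 chromosomes), and Y 6.14 times (p = 0.053, adjusted p = 0.63). By covered length, the ratio was 2.21 for X and 6.55 for Y, and among the 2611 regions with a count at or above the median it was 2.82 for X and 8.48 for Y. No chromosome passed an adjusted p of 0.05 in this permutation test in either direction, and chromosome 2, with 0.15 times the rotated mean, was the only one with an unadjusted p under 0.05 for the number of regions (p = 0.042). For covered length, chromosome 2 (permutation p = 0.018) and Y (p = 0.025) had one, with an adjusted p of 0.30 for both. Rotation carries the many regions of X and Y along, and the central 95% of rotations reached 1504 regions for X and 662 for Y. With so wide a spread, the lack of a call is no evidence against an excess. For the sum of X and Y, chosen after the values were seen, the share of 35.1% lay above the central 95% of rotations, which ran from 1.06 to 34.5% (permutation test by rotation, p = 0.037). X and Y lie side by side in the joined list, and this p-value depends on that order. Placing each region independently, which ignores the clustering, gave 8 chromosomes above and 14 below chance at an adjusted p of 0.05, X and Y among those above.

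Regions on X and Y also had a shorter median length and more counts per kb than those of autosomes. The median length was 1600 bp on X and 2300 bp on Y, against an average of autosomal medians of 3900 ± 508 bp (SD over 22 autosomes), which ranged from 2800 to 5600 bp. The median density was 54.6 counts per kb on X and 97.2 on Y, against 34.1 ± 4.98 on autosomes (SD over 22), which ranged from 28.3 to 48.1. For length and for density, no other choice of 2 of the 24 chromosomes gave a difference from the rest as large (exact permutation test over 276 choices, two-sided p = 0.0036, the smallest it can give). Both comparisons were chosen after the values were seen. Regions of 1 kb or less made up 35.0% of those on X and 29.1% of those on Y, but 3.64% of autosomal regions (123 of 3382). Long regions were not rarer on Y as a whole: those of 10 kb or more made up 11.0% there, 7.81% on autosomes and 0.84% on X. The upper quartile of length was 5600 bp both on Y and over all autosomal regions. Both results for Y rested on its first 3 Mb. Without that stretch, long regions made up 5.17% of those on Y, and the upper quartile of length was 3800 bp. Between regions of equal length, the median count on X was above that on autosomes at 26 of 29 lengths from 0.2 to 6.2 kb (median ratio 1.23), and on Y at 18 of 18 lengths from 0.2 to 6.4 kb (median ratio 2.15). Without regions of 1 kb or less the difference in density was still called (exact permutation p = 0.0072), and that in length did not pass the threshold (medians of 2600 bp on X and 3600 bp on Y against 4045 ± 566 bp, p = 0.094).

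**Figure D2:**
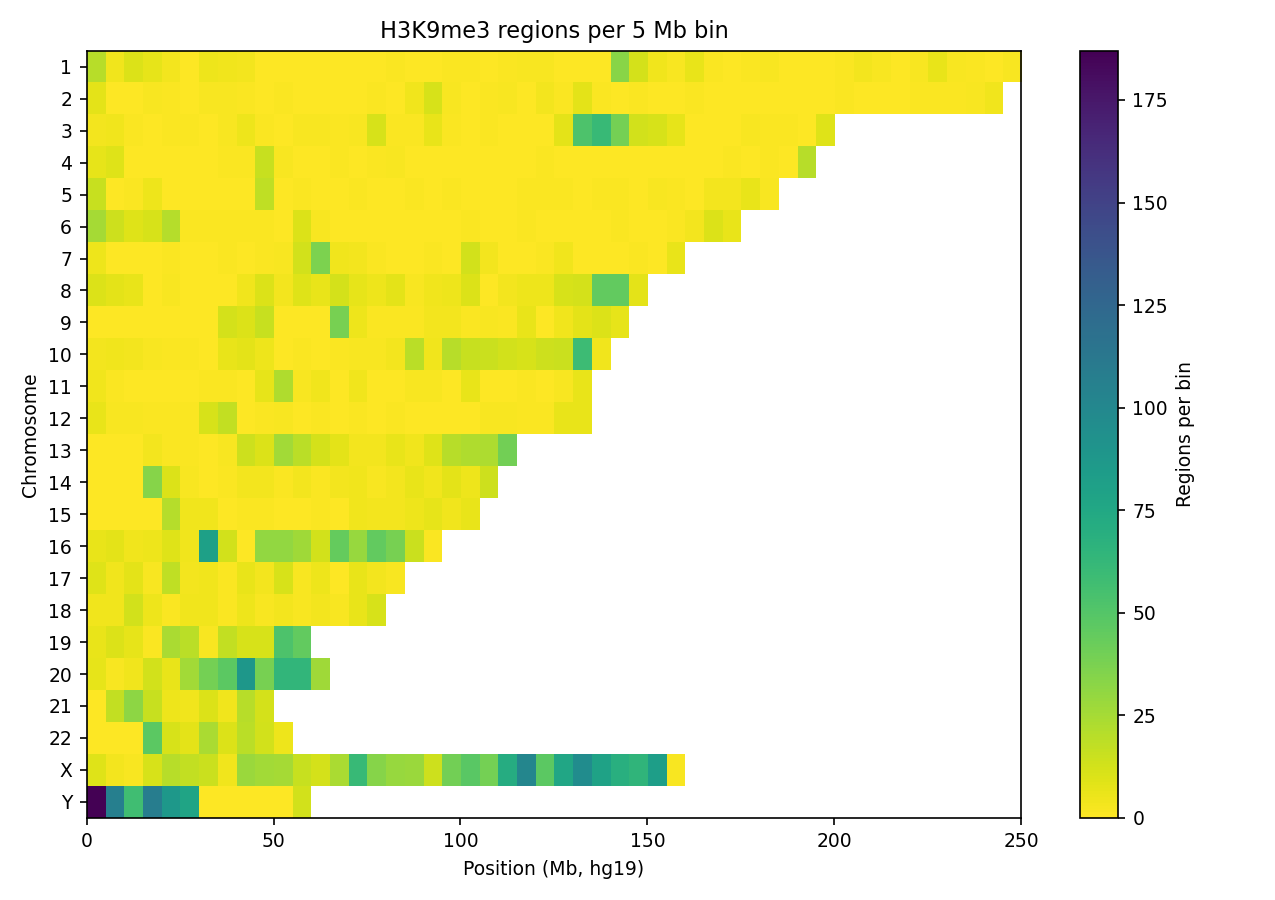
Number of H3K9me3 regions in each 5 Mb bin (colour) by position in Mb on hg19 (x axis) and chromosome (y axis), with each chromosome drawn to the bin of its last region. The start of Y, the distal long arm of X, the long arm of chromosome 20 and part of that of chromosome 3 stand out. So do chromosome 16, with its fullest bin at 30 to 35 Mb, and the long-arm ends of chromosomes 10 and 19. The short arm of chromosome 9 holds no region over most of its length.

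H3K9me3 regions were grouped along the chromosomes. The median gap between neighbouring regions was 56.6 kb, 3.14 times smaller than the 177.6 kb obtained when regions were placed at random within their chromosome (central 95% of 1000 placements 172.3 to 183.2 kb), and none of the placements gave a gap as small. When regions under 100 kb apart were joined, 3930 regions (75.4%) fell into 752 clusters of at least 2, and 1281 stood alone. The cluster with the most regions was at the start of Y (23601 to 2956000), where 133 regions covered 1122.8 kb. It takes in the stretch whose reads cannot be assigned to X or Y. Next were 50 regions on chromosome 20 (40557601 to 42119600, 258.8 kb covered), 49 on chromosome 16 next to the centromere (34233201 to 35285800, 372.8 kb covered), 46 on Y next to the centromere (13104601 to 14627400, 586.6 kb covered) and 43 on chromosome 20 (59354601 to 60498000, 195.8 kb covered). The 2 chromosome 20 clusters had median densities of 28.3 and 28.5 counts per kb, and the 2 on Y had 81.4 and 83.3.

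Of 631 bins of 5 Mb, the 42 with the most regions held 50.6% of all regions, and 196 held none. On autosomes, 16 bins held 40 or more regions, and together they had 879 of the 3382 autosomal regions (26.0%). The long arm of chromosome 20 had 4 of these bins. Neighbouring bins with at least 20 regions each were joined into blocks, a rule chosen after the values were seen. The largest autosomal block ran from the short-arm side of the centromere to the end of the long arm of chromosome 20 (25047001 to 62906800) and held 393 of the 425 regions of that chromosome. A block on chromosome 3 (130206201 to 144626600) held 152 of its 250 regions. Chromosome 16 had 156 of its 402 regions between 65074401 and 84894000 and 87 between 46463201 and 59556800. The end of the long arm of chromosome 13 (95150601 to 114779800) held 105 of 226 regions. On chromosome 19, 97 of 205 regions lay at the end of the long arm (50545401 to 58134600) and 24 between 20198001 and 24631800. Both are parts of the chromosome known for clusters of KRAB zinc finger genes, a family whose members are common H3K9me3 sites, but overlap with genes was not tested. Chromosome 8 had 90 of 245 regions between 135339601 and 144752000, and chromosome 10 had 59 of 232 between 130096201 and 134990400. The median densities of these named blocks lay between 28.4 and 30.7 counts per kb. The remaining bins with 40 or more regions, on chromosomes 16 (30234801 to 34991800) and 22 (16053001 to 19330600), had 33.4 and 37.8. Over all autosomal blocks the range was 27.6 to 48.7.

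Other parts of the genome had no region. Chromosome 4 had the longest stretches without one, 47.4 Mb (123432401 to 170859400) and 41.3 Mb (82154601 to 123432200). On chromosome 9 the first region began at 38441401, so that 38.4 Mb of its short arm held none, whereas on every other chromosome that is not acrocentric the first region began within the first 3 Mb. The threshold behind the list is not known, so a stretch without a region shows no call at that threshold, not an absence of H3K9me3.

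The density of regions changed along X and along Y. With the regions of X cut into 3 parts of equal number, the first 398 (up to 97247000) had a median of 41.1 counts per kb and the last 397 (from 129742401) had 86.7. On Y, the first 212 had 72.5 and the last 212 had 211.3. By 10 Mb bin the median was between 34.1 and 48.6 counts per kb up to 110 Mb and then rose to 52.4, 64.0, 77.5, 94.0 and 96.5. On Y, the median per 5 Mb was 76.3 and 64.5 counts per kb in the first 10 Mb and then 92.7, 120.3, 166.8 and 295 up to 30 Mb. The rank correlation of density with order along the chromosome was 0.54 on X and 0.51 on Y, both past the threshold when the values were rotated along the chromosome (permutation test by rotation, two-sided, p = 0.00084 and p = 0.0016, the smallest each chromosome allows; both have an adjusted p of 0.019 over 24 chromosomes). No autosome passed, and their rho ranged from -0.41 on chromosome 21 to 0.39 on chromosome 12. The smallest p that this permutation test allows ran from 0.0024 on chromosome 20 to 0.016 on chromosomes 2 and 4. Autosomes with few regions could therefore not pass on their own. With regions over 1 kb only, Y had rho = 0.39 and an adjusted p of 0.053, and X still passed (adjusted p = 0.031). With the regions at or above the median count, both passed the same permutation test (adjusted p = 0.031). This relation was chosen after the values were seen, and 48 such relations were computed (density and length on 24 chromosomes). The median length of the 3 parts was 2200, 1800 and 1000 bp on X and 3900, 2000 and 1200 bp on Y. The rank correlation of length with order was -0.24 on X and -0.42 on Y (permutation test by rotation, p = 0.012 and p = 0.0047), and neither passed after adjustment (adjusted p = 0.094 for both). On autosomes it ranged from -0.68 on chromosome 21 to 0.11 on chromosome 1, and none passed, so a fall in length was not particular to X and Y. Set against regions of equal length on the same chromosome, the count still rose along X (rho = 0.48, 1134 regions, permutation test by rotation, p = 0.00088, the smallest it can give) and Y (rho = 0.33, 428 regions, p = 0.014), both unadjusted.

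**Figure D3:**
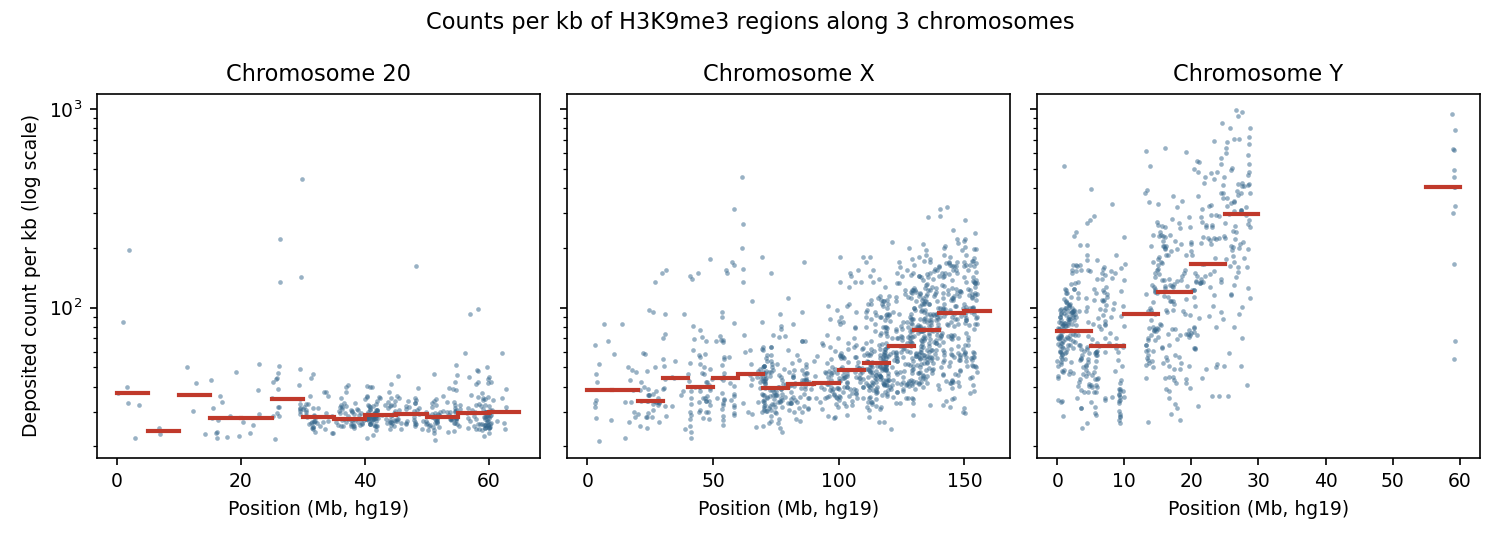
Deposited count per kb (y axis, log scale) of each H3K9me3 region (points) by position in Mb on hg19 (x axis) for chromosomes 20, X and Y, with the median of each 5 Mb bin (10 Mb on X) as a red line. The medians on X go from 38.4 in the first bin to 96.5 in the last, and those of chromosome 20 show no such rise.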

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

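No paired analysis was possible because the list gives no values per library, and no replicate could be left out for the same reason. Of the 50 alternatives computed, 36 kept the direction and stayed on the same side of the threshold or within 1.5 times of the value reported. Chosen after the data were examined were rotation on the spans, every alternative for the comparison of X and Y with autosomes in length and density and for the trends along X and Y, those for the share of X and Y without the start of Y or without short or dense regions, and spacing on autosomes alone. The 2611 regions with a count at or above the median had a median length of 5200 bp and a median count of 174, as selection on the count implies, and formed 402 clusters. Merging regions under 100 kb apart left 2033 intervals over 118.5 Mb, since the gaps were then included, and autosomes alone had 3382 regions. The ratio of X to the rotated mean fell to 2.21 by covered length and 2.82 among those 2611 regions, uncalled as in the full list. A join distance of 500 kb gave 420 clusters. Independent placement in place of rotation, which assumes that regions do not cluster, called 8 chromosomes above and 14 below chance, with X at 4.45 and Y at 6.08 times the mean and no placement as high for either. Without regions of 1 kb or less, the median length on X and Y minus that on autosomes was -945 bp with no call (exact permutation p = 0.094), and the rise of density along Y was no longer called (rho = 0.39). The share of regions, or of covered length, on X and Y lay between 24.5 and 33.4% under its 5 alternatives, against 35.1% as deposited. Planned tests of gene lists, features, gene body position, centromere distance and repeats were not run for want of a genome of the build. The absence of library depths limits every statement on regions that were not called.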

Other observations

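The tests in this part were chosen after the data were examined, except that the count of autosomes with a rising density and the trends at equal length were set out before their values were computed.

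Several blocks of regions next to centromeres had long regions. Beside the centromere of chromosome 21 (10023201 to 14747200), 32 regions had a median length of 9700 bp, and at the start of the long arm of chromosome 22 (16053001 to 19330600) 47 regions had a median of 7600 bp. Chromosome 1 had 33 regions with a median of 7200 bp at 142535401 to 144214000, chromosome 14 had 34 with 6100 bp at 19000001 to 19948600, and chromosome 7 had 37 with 5400 bp at 61059201 to 64957400. The block near the centromere of chromosome 15 (20000201 to 24768200), with 21 regions and a median of 3800 bp, was an exception. Next to those of chromosome 16 (30234801 to 34991800) and chromosome 19 (20198001 to 24631800), 81 and 24 regions had medians of 4800 and 4700 bp. The other blocks named in the report had medians between 3800 and 4400 bp. Of these, that of chromosome 20 runs across the centromere. That of chromosome 16 at 46463201 to 59556800, with a median of 4000 bp, begins on the long-arm side of one. These lengths were not compared by a test.

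The first 2.5 Mb of Y held 118 regions, 18.6% of those on Y, which covered 42.6% of that stretch with 87013 counts. The first 2.5 Mb of X held 0, and the first region on X began at 2944401. This part of both chromosomes is the first pseudoautosomal region, whose X and Y copies have the same sequence in hg19, so short reads cannot be assigned to either. Even placement of such reads on both copies, in ChIP and input alike, would give similar numbers on both. The other pseudoautosomal region lies at the ends of both chromosomes. There, X had 2 regions from 155 Mb on and Y had 11 beyond 59 Mb (exact binomial test, two-sided, p = 0.022, with neighbouring regions taken as independent). A further X region that ended at 154933600 was not among the 2 and may belong to the same stretch. The p-value depends on where these cuts are set. Over the start and end stretches so cut, X had 0.016 times the regions of Y, which argues against even placement. That ratio rests on the start, whose values had been seen and prompted the question. At the end alone it was 0.18, which would not decide. The test was widened from the end to both regions after the end missed its bound. Placement of one kind of library on one copy only, by masking or by the handling of multiple matches, stays open. H3K9me3 on the Y copy alone cannot be told apart from that with 0 regions at the start of X and no reads that separate the copies.

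The rise of density along X and Y may come from several sources. A trend of the assay or caller with position along any chromosome would give a rise on most autosomes, and 9 of 22 had a rho above 0. Regions that become shorter along the chromosome have more counts per kb where the count has a minimum, but the count still rose at equal length, with a rho of 0.48 on X and 0.33 on Y, which argues against shortening as the whole cause. A part of the rise may still come from length. A biological difference along X or Y was not tested.

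The 16 autosomal bins with 40 or more regions, on 8 chromosomes, had a median density of 29.3 counts per kb, against 31.9 in 161 other autosomal bins with at least 5 regions. Collapsed satellite sequence would raise this density. The difference was -2.57 counts per kb (permutation test with 100000 resamples, p = 0.19), and no rise was seen in the crowded bins as a set. This cannot decide on collapse, since the other bins include very dense ones, such as 35 to 40 Mb of chromosome 10 with 170.7 counts per kb. Collapse therefore stays open for the crowded bins. Among these, the fullest bin of chromosome 16 and the crowded bin of chromosome 22 lay above the median of the other bins. A rise in a few regions of a bin would not show in its median. A copy-number gain in the cells used for ChIP against those used for input may also give such blocks; at 29.3 counts per kb and with no input counts it cannot be told apart from broad H3K9me3 domains. These blocks, such as 130206201 to 144626600 on chromosome 3 and the long arm of chromosome 20, would need a comparison with input coverage.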
